A study of Mus musculus with 13 samples.

How the data were processed

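Genomic DNA of mouse E14 embryonic stem cells was amplified and sequenced to count single guide RNAs. Per the labels' protocols, cells were infected with a lentiviral guide library, selected with puromycin for 2 days and then with blasticidin S for 5, 7 or 9 days, and the libraries of Screen I and Screen II were built by different published protocols. The authors deposited 1 table of whole-number counts per guide for 13 libraries, which were read as raw counts since they sum to different totals. MAGeCK is named in the submitters' processing notes without a version. The matching of reads to guides and any filter are not given in the sources used here. Every column was mapped to its sample by name, and 0 columns were left without a sample.

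Groups were taken from the sample titles. Each Screen I group has 1 library, and each of the 4 Screen II groups has 2 replicates. Gene names are those of the file. In a RefSeq gene table of assembly GRCm38.p6, used only for names, 17568 of them are current symbols, 1189 match through 1 synonym and 93 were not matched. Most genes (17575) have 10 guides. The 199 intergenic guides, 0.107% of all guides, stayed in the fits and out of the gene ranking.

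For Screen II, guides with at least 10 counts in at least 2 of the 8 libraries were kept (163285, of which 188 were controls), and genes with at least 3 such guides were tested (18611). All 8 libraries entered 1 fit with group as the only term, TMM scaling and edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), for the contrasts of +blast with -blast early and late, their difference, and late with early -blast. The 1-sided guide p-values were ranked over all guides, and the guides of each gene in the top 10% were combined by robust rank aggregation, with 1e+06 random draws per number of guides, separately for enrichment and depletion, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The lowest p that the draws can give is 1e-06. Since most guides were lost under blasticidin, scaling moved the log2 fold change of the median guide, to -8.09 early, -0.62 late and -0.02 between the -blast groups with TMM and to -9.29, -6.79 and -0.18 with library totals. Effects are therefore given as ranks among guides and as percent of library reads (mean ± SD, n = 2), and a called gene can hold a lower share of reads than without blasticidin. Of 20 gene lists fixed before the data were examined, 19 had members in the file (the olfactory receptor list had 0). They were tested on guide counts with limma's camera (limma 3.58.1), a preset correlation of 0.01 and adjustment over the lists, and again with an estimated correlation. Each list was also counted with gene p-values adjusted over the list alone.

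For Screen I, with 1 library per group, no test was made. The deposited counts were scaled to a library total of 1e+06 (CPM), guides with at least 10 counts in at least 2 of the 5 libraries were kept (141844 guides, 18324 genes with at least 3), and log2((CPM + 1)/(CPM + 1)) was taken per guide and summarised as the median per gene. A gene counted as higher at a median of at least 1 and as lower at -1 or below. Lists and genes were placed among 10000 random guide sets matched on baseline abundance. Shares of reads carry exact Clopper-Pearson 95% intervals, which cover counting error only, since amplified reads without molecular identifiers are not independent molecules. A count of 0 allows up to 3 counts of the total.

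The genes named were set by a rule fixed before the data were examined: per Screen II comparison, up to 10 enriched and 5 depleted genes with the lowest RRA p past the threshold and the same sign in both replicates, all members of the m6A writer, SETDB1, TRIM28 and HUSH, ATRX, DAXX and H3 variant, and LRRC8 lists, and up to 4 members of every other list. In Screen I these were up to 10 genes with the highest day 9 median among those at or above 1 on all 3 days and the 5 lowest between -blast and +puro. The heme synthesis, apoptosome and SPIN1 and SPINDOC lists (3 lists) were written after the Screen II calls were seen. Results for some called genes are not reported here.

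Alternatives were other scalings (DESeq2 1.42.0 with its size factors, edgeR's RLE, library totals, control-guide totals), other filters (no guide filter, 50 counts, 2 guides per gene), RRA on the top 25% or without each gene's strongest guide, counts summed per gene, camera per gene, a fit of 2 groups only, a replicate block, each library left out, and for Screen I pseudocounts of 0.5 and 5 CPM, other filters, size factors, means and the +puro baseline. Added after seeing the data were ranks within 50 abundance bins, +blast counts under 0.1% of the highest count of the same guide in the other stage set to 0, and +blast counts under 20 set to 0.

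The RRA steps were tested on simulated data with known answers. In counts simulated for the late against early -blast comparison (18611 genes), 50 of 50 genes raised 2-fold and 49 of 50 lowered 2-fold were recovered, with 0 unchanged genes called enriched and 2 called depleted. In counts simulated for the early blasticidin comparison (18611 genes), where single guides survive, 80 of 100 genes were recovered with 60% of their guides raised and 7 of 100 with 30%, with 1 unchanged gene called enriched and 40 called depleted. A gene with few active guides could thus be missed. These simulated counts took their spread from the -blast libraries, and the early +blast shares were shuffled over guides. The real +blast replicates spread more, so the numbers of recovered and wrongly called genes may not hold for them. Replicates were compared by chi-square over guides, with chi-square per degree of freedom of 330.4 (early +blast), 457.5 (late +blast), 6.62 (early -blast) and 3.82 (late -blast), all above counting error, which does not exclude repeat amplification of the same DNA. Numerical work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.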

Results

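Mouse E14 embryonic stem cells, a line that keeps its pluripotent state in medium with serum and leukaemia inhibitory factor, carried a reporter cassette of IAPEz, an endogenous retrovirus of the mouse genome. The cells were infected with a lentiviral library of single guide RNAs for Cas9 knockout and were selected with puromycin and then with blasticidin S, an antibiotic that blocks translation. Guide abundance was counted from genomic DNA for 185836 guides against 18850 genes, of which 199 guides were intergenic controls. Screen I had 5 libraries with 1 sample each, taken after puromycin (+puro), without blasticidin (-blast) and after 5, 7 or 9 days of blasticidin. Screen II had 8 libraries in 4 groups of 2 replicates, early and late, with blasticidin (+blast) and without it. The labels do not define early and late in days, and nothing in them says that replicates came from separate cultures. The guide p-values therefore measure only the spread between these samples, pooled over the 8 libraries, which may be technical. Replicates differed far more in the +blast groups (chi-square per degree of freedom 330.4 early and 457.5 late) than in the -blast groups (6.62 and 3.82). The pooled spread therefore need not match that of the groups compared. Gene p-values from robust rank aggregation compare the ranks of a gene's guides with random ranks and do not measure the spread between libraries. Total counts ranged from 27330151 to 35389737 per library in Screen II. In Screen I they were 20465694 for +puro, 7550714 for -blast, 10673626 at day 5, 10371631 at day 7 and 5442815 at day 9.

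The libraries with blasticidin had more guides without a count and more of their reads in a few guides than those without it. In Screen I the share of guides with a count of 0 was 11.9% without blasticidin, 35.6% at day 5, 63.1% at day 7 and 85.7% at day 9. In Screen II it was 86.1% and 84.6% in the early +blast replicates and 51.5% and 40.5% in the late +blast replicates, against 6.78% to 8.77% in the 4 -blast libraries. The 100 most abundant guides held 57.4% and 58.3% of the reads of the early +blast libraries and 66.2% and 59.4% of the late ones, against at most 1.33% without blasticidin. The replicates of a +blast group shared 96 (early) and 98 (late) of these 100 guides. Early and late +blast libraries shared 3 or 4 of theirs. The labels do not say that the selection was repeated for each replicate, so the SD (n = 2) may not cover how it varies. The median gene held 0.00514% of reads in early -blast and 2.38e-05% in early +blast, and 0.00496% and 9.88e-05% in the late groups. Intergenic control guides together held 0.130% of reads in early -blast and 0.0644% in early +blast, and 0.133% and 0.0793% in the late groups. Few of them kept counts: 4 and 6 had at least 100 in the early +blast replicates, against 142 and 136 in early -blast. In late +blast these were 10 and 11, against 136 and 131. With library totals the median control guide changed by a log2 value of -9.915 early and -6.799 late, against -9.293 and -6.785 for the median guide.

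**Figure D1:**
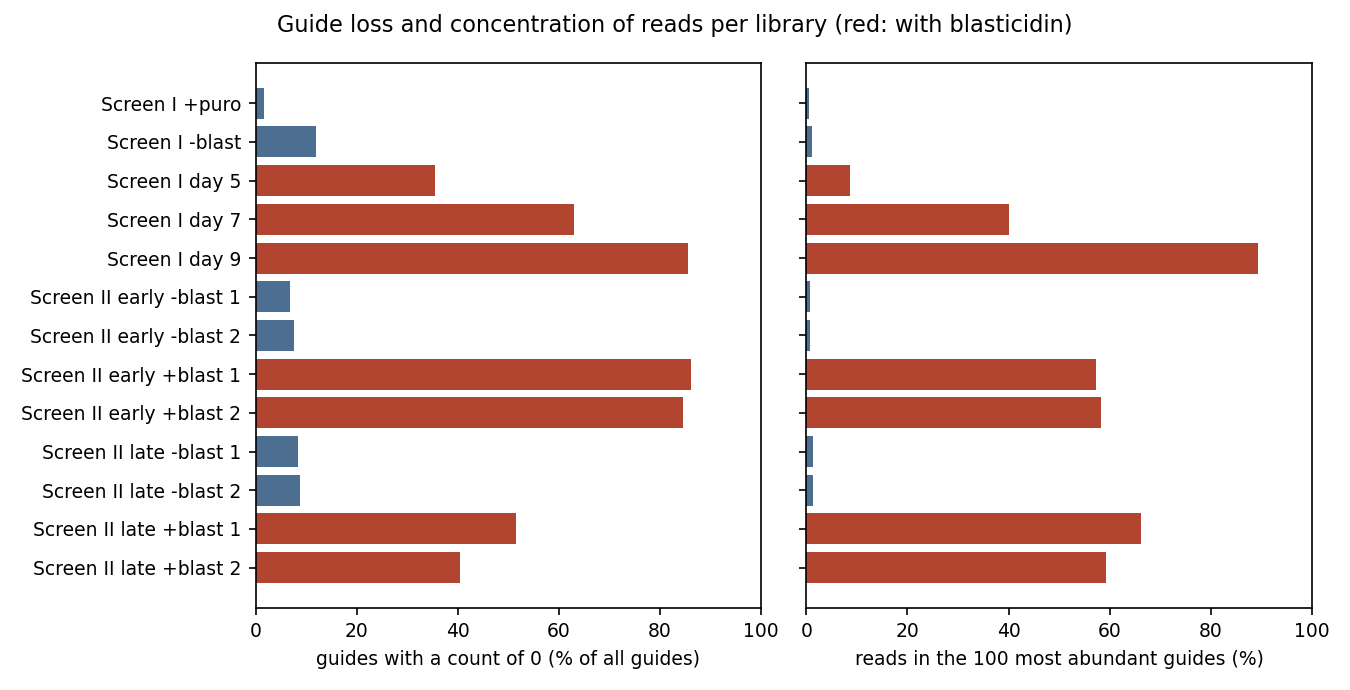
Bars show, for each of the 13 libraries, the share of guides with a count of 0 (left, % of all guides) and the share of reads in the 100 most abundant guides (right, %), with blasticidin in red and without it in blue. At day 9 of Screen I 85.7% of guides had no count and the 100 most abundant guides held 89.3% of reads.

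The early comparison of Screen II asked which knockouts were over-represented among cells grown with blasticidin. Guides against 24 genes were enriched, led by Daxx, a histone chaperone, whose share of reads was 0.000617% ± 2.30e-05 without blasticidin and 2.92% ± 0.0671 with it (SD, n = 2). Guides against AI846148 (current symbol Spindoc), which encodes a binding partner of the chromatin reader Spin1, went from 0.00313% ± 0.000305 to 4.31% ± 0.167, and guides against Spin1 itself from 0.00275% ± 4.25e-05 to 2.66% ± 0.0938. Guides against other genes, among them Casp9, Hccs, Fech and Cpox, were enriched relative to other guides with much smaller read shares. All 9 guides against Casp9, the initiator caspase of that route, and all 9 against Hccs, which attaches heme to cytochrome c, were among the top 10% of guides.

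These results came from edgeR's quasi-likelihood test on 163285 guides, followed by robust rank aggregation (RRA) over the guides of 18611 genes, and enriched here means ranked high among all guides. The adjusted p was 0.00143 for each of Daxx (7 of 7 guides in the top 10%), Spindoc (6 of 9), Spin1 (6 of 9), Casp9, Hccs, Morc3 (7 of 9), Tamm41 (8 of 9), Fech (8 of 9), Cpox (9 of 10) and Trp53 (9 of 10). Morc3, an ATPase of the nuclear MORC family, went from 0.00108% ± 3.31e-05 of reads to 0.0578% ± 0.00466, and Tamm41, a mitochondrial enzyme of cardiolipin synthesis, from 0.00109% ± 0.000109 to 0.00255% ± 0.000762. Casp9 went from 0.00714% ± 0.000319 to 0.0124% ± 0.00185, and the Hccs shares of 0.0134% ± 0.000383 and 0.0161% ± 0.00515 differed by less than the larger SD. The read share of 10 of the 24 genes was lower with blasticidin. Among them were Fech (0.00835% ± 0.000345 to 0.00479% ± 0.00185) and Cpox (0.00886% ± 0.000580 to 0.00339% ± 0.00120), both enzymes of heme synthesis, and the tumour suppressor Trp53 (0.176% ± 0.00103 to 0.0552% ± 0.00641). Over the same libraries the median gene's share changed 0.00483-fold. Of the called genes outside the naming rule, which were looked at after their values were seen, Pias2, a SUMO ligase, had the largest share (0.00384% ± 0.000420 to 2.63% ± 0.0595), with 4 of 8 guides in the top 10%. Others were Apaf1, Urod, Uros, Ppox, Socs3, Bex6 and Dph3. A single guide against Pias2 held 2.47% of early +blast reads, most of the share of that gene. Single guides against Spindoc held 2.35% and 1.69%. No gene passed as depleted by this test (0 genes; 1005 at an unadjusted p under 0.05), 0 did with DESeq2, 1 with only the 4 early libraries in the fit and 6052 with counts summed per gene, where 2432 were enriched. With 86.1% and 84.6% of guides at a count of 0 in the early +blast replicates, a gene could hardly rank below the rest. The absence of depleted genes therefore says little. Ranking guides within bins of their -blast abundance ended the Trp53 call (adjusted p 0.981, range over 20 alternatives 8.04e-05 to 0.981), as did the fit without early +blast replicate 1 (0.175).

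The m6A writer complex methylates adenosines of mRNA. In the early comparison, of its 8 measured members, 2 passed over all genes, Mettl14 and Wtap, and 4 passed adjusted over the list alone, with the catalytic subunit Mettl3 and 1110037F02Rik (current symbol Virma) added. The read share of 4 members was lower with blasticidin: Mettl3 (0.0119% ± 0.000856 and 0.00449% ± 0.000849), Rbm15 (0.00833% ± 0.000102 and 0.000206% ± 0.000278), Zc3h13 (0.00523% ± 0.000488 and 0.00153% ± 0.00176) and Cbll1 (0.00707% ± 0.000862 and 3.66e-06% ± 5.17e-06). Mettl14, the partner of Mettl3, went from 0.0122% ± 0.000848 of reads to 0.0185% ± 0.00355 (6 of 10 guides in the top 10%, adjusted p = 0.00837), and Wtap, the adaptor subunit, from 0.0127% ± 0.00139 to 0.0203% ± 0.00256 (4 of 10 guides, adjusted p = 0.0434). In all, 25 of the 74 guides against the list (33.8%) were in the top 10%. Limma's camera test put the list up with an adjusted p of 2.53e-06 (adjusted p = 0.227 with an estimated correlation). The study's title names m6A, so the list is not independent evidence of its direction. The Wtap call was lost in 13 of 20 alternatives (adjusted p 0.000786 to 0.597) and the Mettl14 call in 4 of 20 (0.000631 to 0.168), in both cases with guides ranked within abundance bins. Without early +blast replicate 2 the adjusted p was 0.168 for each, and Wtap was also lost without early +blast replicate 1 (0.597), early -blast replicate 1 (0.35) and early -blast replicate 2 (0.561).

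Guides against genes of retroviral silencing were enriched for few members of each list. Of 9 measured members of the SETDB1, TRIM28 and HUSH list, 1 passed, 2810474O19Rik (current symbol Resf1), over all genes and adjusted over the list alone. Its share went from 0.00289% ± 0.000287 to 0.353% ± 0.00294 (4 of 10 guides, adjusted p = 0.00207). Setdb1, the H3K9 methyltransferase of that list, had 2 of 3 guides in the top 10% and Trim28, its corepressor, had 3 of 5, and neither passed. The Setdb1 share was lower with blasticidin (0.000452% ± 5.19e-05 to 2.34e-05% ± 2.89e-05), close to the median gene at 2.38e-05%. That of Trim28 was 0.0008115% ± 0.0001926 and 0.002057% ± 0.0006525. Of 9 measured members of the ATRX, DAXX and histone H3 variant list, 3 passed over all genes and adjusted over the list alone: Daxx, Morc3 and Atrx, a chromatin remodeller, which went from 0.00131% ± 6.80e-05 to 0.182% ± 0.00154 (4 of 8 guides, adjusted p = 0.00207). Camera put the first list up with an adjusted p of 1.35e-05 (adjusted p = 0.227 with an estimated correlation) and the second with 1.69e-07 (adjusted p = 0.299 with an estimated correlation). The call for Resf1 ended in 2 of 20 alternatives (5.29e-05 to 0.096) and that for Atrx in 2 of 20 (1.07e-06 to 0.134), without early +blast replicate 1 (0.0713) and without early +blast replicate 2 (0.134).

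Camera placed 9 of 19 lists up in the early comparison, and 0 with an estimated correlation (4 at an unadjusted p under 0.05). Besides those above, these were the SUMO and CAF-1 list (adjusted p = 3.69e-05, then 0.227 as the adjusted p with an estimated correlation), the RNA exosome and NEXT list (0.00071, then 0.444), growth restraint (0.00515, then 0.507), self-renewal factors (0.0271, then 0.521), ribosomal proteins (1.90e-05, then 0.227) and the proteasome (0.00566, then 0.521). Trp53 was the 1 member of growth restraint that passed, and 0 of the 9 SUMO and CAF-1, 13 exosome, 10 self-renewal, 44 ribosomal and 30 proteasome members tested passed in RRA. The median log2 fold change of the self-renewal members was -0.10 relative to all genes, on the other side from its camera direction. Without early +blast replicate 1 growth restraint (0.125), self-renewal factors (0.125) and the proteasome (0.0905) were lost, and self-renewal factors also without early +blast replicate 2 (0.0998) and early -blast replicate 1 (0.117). Within abundance bins, ribosomal proteins (11.9% of guides in the top 10%), the proteasome (13.6%) and self-renewal factors (14.7%) lay inside the random range. The central range of random guide sets ended at 14.29%, 14.77% and 17.65%. For these lists -blast abundance thus stays open as a cause of the camera call. The other called lists lay above their range, the nearest being the exosome list (18.2%, end at 16.9%) and SUMO and CAF-1 (22.2%, end at 20%). Adjusted over the list alone, Dnmt1 and Uhrf1 of the DNA methylation list, which maintain CpG methylation, and Grb2 and Flcn of the list for exit from the naive state passed, and 0 did over all genes. The LRRC8 anion channel subunits are known to carry blasticidin into cells. Of the 5 members 0 passed, Lrrc8a had 0 and Lrrc8d 2 of its guides in the top 10%, and the list's adjusted p was 0.439. Readers and erasers of m6A (0.631), other RNA methyltransferases (0.443), other H3K9 factors (0.0754), PRC2 (0.439), PRC1.6 (0.123), mRNA decay (0.0754), DNA methylation (0.0513), exit from the naive state (0.254) and the response to stalled ribosomes (0.338) did not pass in camera.

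**Figure D2:**
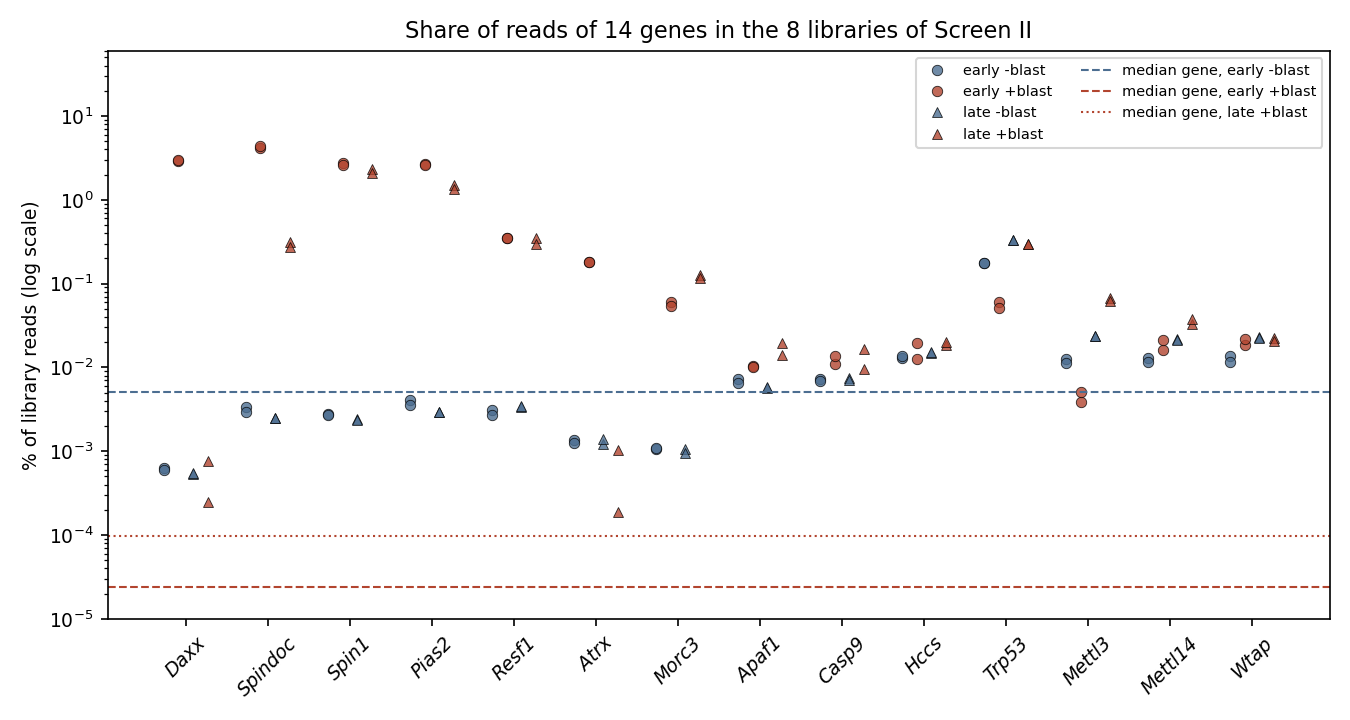
Points show the share of library reads (%, log scale) of 14 genes in each of the 8 Screen II libraries, circles for early, triangles for late, blue without and red with blasticidin, and horizontal lines give the median gene of 3 groups. Spindoc is listed as AI846148 and Resf1 as 2810474O19Rik in the file. Daxx lies at 2.92% in early +blast and at 0.000501% in late +blast (means of 2 libraries).

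The late comparison asked the same question in the late libraries. Guides against 20 genes were enriched, again with Spin1, which went from 0.00240% ± 2.79e-05 of reads without blasticidin to 2.21% ± 0.204 with it (SD, n = 2). Guides against Pias2 went from 0.00293% ± 1.80e-05 to 1.42% ± 0.108, those against Resf1 from 0.00344% ± 4.80e-05 to 0.322% ± 0.0366, and those against Spindoc from 0.00250% ± 2.51e-05 to 0.291% ± 0.0272. A single guide against Pias2 held 1.20% of late +blast reads, and it was not the guide that led early. Resf1 guides with mean counts of 38289 and 66712 in early +blast had 4 and 330 in late +blast. All guides against Apaf1, the scaffold of the apoptosome (10 of 10), Casp9 (9 of 9) and Hccs (9 of 9) were again in the top 10%. Guides against Daxx passed the test, yet their share was 0.000544% ± 7.81e-06 without and 0.000501% ± 0.000362 with blasticidin.

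By edgeR and RRA the adjusted p was 0.00207 for Spin1 (6 of 9 guides), Spindoc (5 of 9), Resf1 (5 of 10), Apaf1, Casp9, Hccs, Daxx (7 of 7) and Trp53 (8 of 10), and 0.00338 for Pias2 (3 of 8). Apaf1 went from 0.00576% ± 2.82e-05 to 0.0167% ± 0.00389 of reads, while the shares of Casp9 (0.00731% ± 0.000377 and 0.0130% ± 0.00479) lay within 2 SD. Trp53 held 0.333% ± 0.00165 without and 0.298% ± 0.00365 with blasticidin, against a median gene whose share changed 0.0195-fold. Other called genes, chosen after their values were seen, were Urod, Ppox and Uros of heme synthesis, the RNA-binding protein Elavl1 (0.00286% ± 4.86e-05 to 0.0587% ± 0.0167), the splicing factor Tra2b, the translation repressor Eif4ebp1, and Tsc2, Mettl3, Grb2 and Morc3 from the lists. No gene passed as depleted (0 genes; 948 at an unadjusted p under 0.05), 0 did with DESeq2 and 3390 with counts summed per gene, where 1468 were enriched. The late +blast replicates had 51.5% and 40.5% of guides at a count of 0, which limits what could rank as depleted. The count of 20 was 12 without late +blast replicate 2 and 12 without late -blast replicate 2, 13 within abundance bins, 11 with a minimum of 50 counts and 12 with library totals as the scale. Pias2 was lost without its strongest guide (0.116; range 0.000123 to 0.116).

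In the late +blast libraries the 6 Daxx guides with at least 10000 counts in early +blast had mean counts of 1.5 to 27. The median of their late over early count was 0.00642%, and 407 guides of other genes at that early abundance had a median of 0.0151% (5th to 95th percentile 0.00410% to 6.18%). With +blast counts under 0.1% of a guide's highest count in the other stage set to 0, an alternative added after seeing the data, Daxx no longer passed late (adjusted p = 1, range over 20 alternatives 4.56e-08 to 1), and Morc3 did not either (0.0725; range 0.000142 to 0.785). That setting took all late +blast counts of the 6 Daxx guides to 0 whatever their source, so the lost call does not tell where they came from. Unlike Daxx, Morc3 held a higher share of late reads with blasticidin (0.121% ± 0.00616) than without it (0.00101% ± 6.70e-05), and also than in early +blast. All 24 early calls remained with that setting, as did 18 of the 20 late calls. Morc3 was also lost without late +blast replicate 1 (0.631) and without late +blast replicate 2 (0.785), and Daxx with library totals as the scale (0.407) and with +blast counts under 20 set to 0 (0.551). The latter setting ended 6 early calls (Bex6, Dph3, Ppox, Socs3, Uros and Wtap) and 5 late calls (Daxx, Eif4ebp1, Elavl1, Morc3 and Tsc2).

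**Figure D3:**
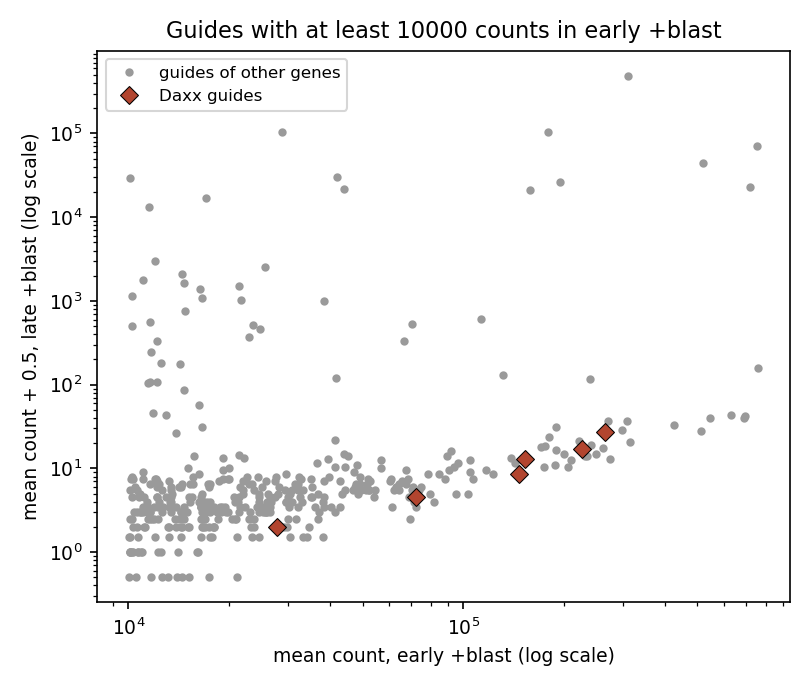
Each point is a guide with at least 10000 mean counts in early +blast (x axis, log scale), with its mean count plus 0.5 in late +blast on the y axis (log scale), Daxx guides as red diamonds and 407 guides of other genes in grey. The Daxx guides lie in the band of guides with few late counts, between 1.5 and 27.

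In the late comparison the m6A writer list was up in camera with an adjusted p of 0.00165 (adjusted p = 0.0625 with an estimated correlation). Of its 8 members, 1 passed over all genes, Mettl3, and 3 passed adjusted over the list alone, Mettl3, Mettl14 and Wtap. Mettl3 went from 0.0238% ± 0.000200 of reads to 0.0645% ± 0.00426 (6 of 8 guides, adjusted p = 0.0226). Mettl14 was at 0.0215% ± 0.000452 and 0.0354% ± 0.00369 (adjusted p = 0.463), and Wtap at 0.0228% ± 0.000407 and 0.0217% ± 0.00123 (adjusted p = 0.707). Of the 74 guides against the list, 31.1% were in the top 10%. The Mettl3 call ended in 4 of 20 alternatives, among them the fit without late +blast replicate 2 (0.0898) and ranks within abundance bins (0.104), over a range of 9.64e-05 to 0.134. The list itself was lost without late +blast replicate 2 (adjusted p = 0.0524).

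The SETDB1, TRIM28 and HUSH list was up with an adjusted p of 0.00188 (adjusted p = 0.0625 with an estimated correlation), with Resf1 as its 1 member past the threshold over all genes and adjusted over the list alone. With a gene-level set statistic the SETDB1, TRIM28 and HUSH list was lost (adjusted p = 0.732, range over 16 alternatives 1.43e-05 to 0.732). Growth restraint had the lowest late list p (adjusted p = 6.50e-05, and 0.0625 as the adjusted p with an estimated correlation). Trp53 and Tsc2, an inhibitor of mTOR signalling (0.00227% ± 8.49e-05 to 0.00486% ± 0.000658, adjusted p = 0.0172), passed over all genes, and 5 of 14 members did adjusted over the list alone, with Tsc1, Nprl2 and Zfp292 added. Tsc2 was lost without late +blast replicate 1 (0.485), late +blast replicate 2 (0.171), late -blast replicate 1 (0.233) and late -blast replicate 2 (0.272). No list held with an estimated correlation (0 lists; 3 at an unadjusted p under 0.05). The ATRX, DAXX and H3 variant list was not called (0.401), with Daxx and Morc3 past the RRA threshold and Atrx at 0.000608% ± 0.000597 of reads with blasticidin (adjusted p = 1). Grb2, an adaptor of growth factor signalling in the list for exit from the naive state, passed over all genes (3 of 9 guides, adjusted p = 0.0341) and its list did not (0.730). It was lost without late +blast replicate 1 (0.235), late +blast replicate 2 (0.106), late -blast replicate 1 (0.252) and late -blast replicate 2 (0.282). Adjusted over the list alone, Ptpn11 of the same list, Dnmt1 and Tet1 of DNA methylation and Prdm14 of self-renewal passed. Of the LRRC8 channel members 0 passed and the list's adjusted p was 0.730. The other 13 lists had adjusted p between 0.374 and 0.823.

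The difference of the blasticidin effect between late and early was tested as an interaction. Guides against Daxx had a lower effect late than early, with a read share of 2.92% ± 0.0671 in early +blast and 0.000501% ± 0.000362 in late +blast (SD, n = 2; 6 of 7 guides in the lowest 10%, adjusted p = 0.0186). Guides against Cpox, an enzyme of heme synthesis, were also lower (7 of 10 guides, adjusted p = 0.0465), at 0.00339% ± 0.00120 in early +blast and 0.000888% ± 0.000366 in late +blast, while without blasticidin they went from 0.00886% ± 0.000580 to 0.0139% ± 0.00112. No gene had a higher effect late by edgeR and RRA (0 genes; 1024 at an unadjusted p under 0.05), 0 did with DESeq2, and 2334 did with counts summed per gene. The Daxx difference held in all 23 alternatives (adjusted p 1.99e-17 to 0.0188) and the Cpox difference was lost in 14 of 23 (0.00931 to 0.983). For Cpox these included the fits without early +blast replicate 1 (0.0558), early +blast replicate 2 (0.983), early -blast replicate 1 (0.143), early -blast replicate 2 (0.0791), late +blast replicate 1 (0.158), late -blast replicate 1 (0.0806) and late -blast replicate 2 (0.0806).

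Relative to other guides, camera placed 3 lists lower late than early: ATRX, DAXX and H3 variants (adjusted p = 0.000476, and 0.346 as the adjusted p with an estimated correlation), SUMO and CAF-1 (0.00785, then 0.346) and ribosomal proteins (0.00785, then 0.162). Their median members lay at log2 values of -1.62, -2.68 and -1.43 relative to all genes. The median over all genes was itself 5.15 with TMM and 2.29 with library totals. The direction is thus relative to other guides, and the scale leaves open whether the lists themselves fell. Daxx was the 1 member of the first list past the RRA threshold over all genes, and Daxx and Atrx passed adjusted over the list alone. In the SUMO and CAF-1 list 0 of 9 members and among ribosomal proteins 0 of 44 passed over all genes or adjusted over the list alone. The m6A writer list did not differ by this test (adjusted p = 0.748), with Mettl3 higher and Virma lower late adjusted over the list alone. These calls were not kept when single libraries were left out, which leaves 1 library in a group, and the cause was not tested. Without late +blast replicate 2 all 3 were lost (0.076, 0.0957 and 0.224 in the order above), without early +blast replicate 1 SUMO and CAF-1 (0.0677) and ribosomal proteins (0.191), and without late +blast replicate 1 SUMO and CAF-1 (0.0565). No list held with an estimated correlation (0 lists; 2 at an unadjusted p under 0.05).

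The comparison of late with early libraries without blasticidin asked which knockouts differed in abundance between them. The labels do not say that the late cells were grown on from the early ones, so fell and rose mean lower or higher late than early. Guides against Gfm2, a factor of mitochondrial ribosome recycling, fell from 0.00548% ± 1.10e-05 to 0.00152% ± 0.000116 of reads (SD, n = 2; 9 of 9 guides in the lowest 10%, adjusted p = 0.00931). Guides against Urm1, needed for tRNA thiolation, fell from 0.00187% ± 0.000170 to 0.000799% ± 2.89e-05 (6 of 9, adjusted p = 0.00931), and those against Trmu, which thiolates mitochondrial tRNAs, from 0.00409% ± 0.000243 to 0.00195% ± 4.28e-05 (7 of 9, adjusted p = 0.0124). Rilpl2 (adjusted p = 0.0140), the pseudouridine synthase Pus7 (0.0186) and Commd4 (0.0403, named after its value was seen) also fell. Guides against Gpi1, an enzyme of glycolysis, rose from 0.00541% ± 3.40e-05 to 0.00751% ± 0.000225 (7 of 9, adjusted p = 0.0186).

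No list passed in this comparison (0 of 19 in camera, 2 at an unadjusted p under 0.05, 1 with DESeq2). The m6A writer list had the lowest adjusted p (0.239, and 0.611 as the adjusted p with an estimated correlation) and passed in 7 of 16 alternatives (4.88e-14 to 0.611), with Mettl3 at 0.0119% ± 0.000856 early and 0.0238% ± 0.000200 late, Mettl14 at 0.0122% ± 0.000848 and 0.0215% ± 0.000452, and Wtap at 0.0127% ± 0.00139 and 0.0228% ± 0.000407. In a fit of the 4 -blast libraries alone, 39 genes were enriched and 9 depleted, and Mettl3 (0.00143), Wtap (0.00143) and Mettl14 (0.0257) were among the enriched. That fit did not pool its spread with the +blast libraries. With library totals as the scale 6 genes were enriched and 5 depleted, against 1 and 6 here. The enriched count was 0 without early -blast replicate 1 and 0 without late -blast replicate 2, fits that gave 3 and 10 depleted genes. In these fits Gpi1 had adjusted p of 0.798 and 0.167, Trmu of 0.324 and 0.0806, and Pus7 of 0.0931 and 0.122. Without early -blast replicate 2 Pus7 (0.482) and Rilpl2 (0.864) were lost, and Rilpl2 also without late -blast replicate 2 (0.482). With counts summed per gene 0 genes passed in either direction.

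In Screen I, the -blast library compared with the +puro library showed losses during culture without blasticidin. There was 1 library on each side, so the values have no replicate check and no p-value, and exact Clopper-Pearson intervals (95%) cover counting error only. The median guide log2 ratio was -1 or below for 572 of 18324 genes. The lowest were Dph6 (-2.83), Hsd17b10 (-2.82), Mecr (-2.74), L3mbtl2 (-2.62) and Dph5 (-2.56). Dph5 and Dph6 act in diphthamide synthesis on elongation factor 2, Hsd17b10 and Mecr are mitochondrial enzymes, and L3mbtl2 belongs to a Polycomb complex. Hsd17b10 held 0.0111% of +puro reads (interval 0.0106% to 0.0115%) and 0.000861% of -blast reads (0.000664% to 0.00110%). The count of 572 was 13 with a pseudocount of 5 CPM and 962 with 0.5 CPM. Guides against the m6A writer list were higher: 35.7% of its 70 guides were in the top 10%, against 12.1% in random guide sets of the same abundance, and its median of 0.51 lay above all 10000 of them. The ATRX, DAXX and H3 variant list had 33.8% of its 68 guides there, against 9.63% (0 of 10000 random sets had as many), and the mRNA decay list 19.7% of 137, against 9.08% (1 of 10000). The growth restraint list had a median of -0.51, below all 10000 random sets, while 17% of its guides were in the top 10%, against 11.6% (536 of 10000).

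Against the -blast library, guides of 357 genes had a median log2 ratio of at least 1 at day 5, 102 at day 7 and 7 at day 9 of blasticidin. The 3 genes at or above 1 on every day were Apaf1 (4.98, 5.07 and 1.99 at days 5, 7 and 9), Casp9 (5.18, 4.85 and 1.27) and Hccs (5.51, 4.94 and 1.20). Apaf1 held 0.00593% of -blast reads (interval 0.00540% to 0.00651%), 0.232% at day 5 (0.229% to 0.235%), 0.242% at day 7 (0.239% to 0.245%) and 0.0246% at day 9 (0.0233% to 0.0260%). The 3 time points share 1 -blast library. In 20 simulations of unchanged libraries against it, the highest count of genes at or above 1 on all 3 days was 0, and independent lists would share 0.000759. Unchanged libraries lack the loss of guides seen under blasticidin, so these draws do not show what that loss alone would give. The counts changed with the scale and filter, to 31, 22 and 3 with a pseudocount of 5 CPM and to 259, 225 and 39 with median-of-ratios size factors.

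The m6A writer list stood above random guide sets at every time point, with 27.1%, 30.0% and 37.1% of its 70 guides in the top 10% at days 5, 7 and 9, against 9.09%, 9.02% and 9.44%. Mettl14 had a median log2 ratio of 2.23 at day 9 with 9 of 10 guides in the top 10%, and 0 of 10000 random sets had as many. It held 0.0144% of -blast reads (interval 0.0136% to 0.0153%) and 0.170% at day 9 (0.166% to 0.173%). Wtap went from 0.0182% of -blast reads (0.0173% to 0.0192%) to 4.22% at day 9 (4.2% to 4.24%), with 2 of 9 guides in the top 10% and a median of -2.76, and 1 guide held nearly all of these day 9 reads (4.22%). Mettl3 had 3 of 9 guides in the top 10% at day 9 and a median of -1.37. Growth restraint had 30.4%, 25% and 20.5% of 112 guides in the top 10%, against 9.21%, 9.44% and 9.30% in random sets. Other lists stood above random sets on some days. Self-renewal factors had 33.3% at day 5, against 15.7%, and 35.1% at day 9, against 22.6%. DNA methylation had 23.5% at day 7, against 10.8%, and ATRX, DAXX and H3 variants 23.5% at day 9, against 13.4%. These 3 lists lay nearer to random sets on their other days. Of the LRRC8 channel list 18.6%, 14% and 9.30% of 43 guides were there, against 11.9%, 11.2% and 14.7% in random sets. Atrx had 6 of 7 guides in the top 10% at day 9, which 3 of 10000 random sets reached, and went from 0.00240% of reads (0.00206% to 0.00277%) to 0.591% (0.584% to 0.597%). Daxx was at 0.000689% of -blast reads (0.000514% to 0.000903%), 0.0193% at day 5 (0.0185% to 0.0201%), 0.0473% at day 7 (0.0459% to 0.0486%) and 0.00233% at day 9 (0.00195% to 0.00278%). Resf1 held 0.00155% of -blast reads (0.00128% to 0.00186%) and 0.0257% at day 9 (0.0244% to 0.0271%), with 2 of 7 guides in the top 10%. For the SETDB1, TRIM28 and HUSH list 20.8%, 22.9% and 33.3% of 48 guides were in the top 10% at days 5, 7 and 9, against 14%, 13.5% and 17.1% in random sets, of which 1173, 479 and 3 of 10000 had as many. Between -blast and +puro the median of this list was -1.04, below all 10000 random sets. For self-renewal factors it was -0.83 and for growth restraint -0.51. The same -blast library is the base of the day 5, 7 and 9 ratios, so low -blast counts alone would raise them. The random sets were matched on baseline abundance and do not remove this link, and its part in the shares of these lists was not tested.

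**Figure D4:**
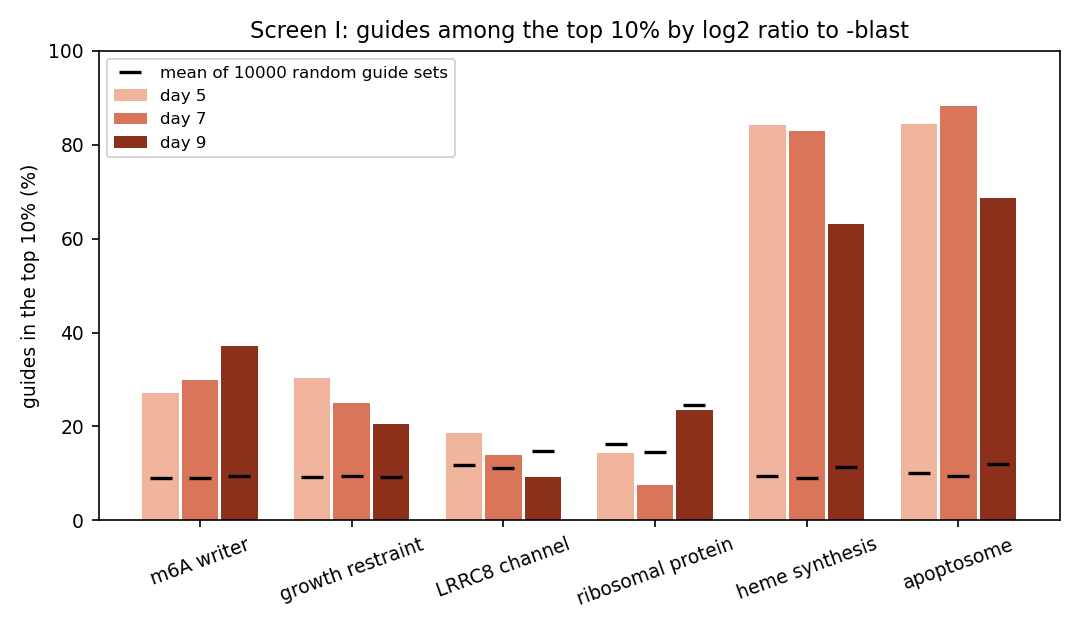
Bars show the share of a list's guides (%) among the top 10% of guides by log2 ratio to the -blast library at days 5, 7 and 9 of Screen I, and black marks the mean of 10000 random guide sets matched on abundance. The m6A writer bars are at 27.1%, 30.0% and 37.1%, and the heme synthesis and apoptosome lists were written after the Screen II calls were seen.

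The overlap of the screens asked whether the late calls of Screen II also stood out in Screen I. Of the 20 late genes, 3 were among the 7 genes at or above 1 at day 9, Apaf1, Casp9 and Hccs, where 0.00766 were expected among 18283 genes in both (Fisher's exact test, 2-sided, p = 3.91e-08). Against day 5 the overlap was 14 of 20 (Fisher's exact p = 2.49e-20), adding among others Spin1, Spindoc, Pias2, Daxx, Elavl1, Trp53, Tsc2, Urod, Uros and Ppox, and against day 7 it was 12 (exact p = 4.40e-23). The early calls shared 4 genes with day 9, with Mettl14 added (Fisher's exact p = 7.97e-11). With a log2 ratio of at least 2 at day 9 the overlap was 0 of 2 genes (exact p = 1). Within Screen II, 14 genes were called both early and late, where 0.0258 were expected by chance (Fisher's exact test, 2-sided, p = 1.11e-38). They include Daxx and Morc3, whose late calls ended with low counts of guides abundant in the other stage set to 0. The late read share changed 120-fold for Morc3 and 0.921-fold for Daxx. The early and late comparisons used different -blast libraries but shared 1 estimate of the spread.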

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

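The tests of the late Daxx counts below were chosen after the result was seen. The blasticidin effect differed between the late and early libraries of Screen II for 2 genes, by a test of the difference itself. For Daxx the adjusted p was 0.0186, with 2.92% ± 0.0671 of reads in early +blast and 0.000501% ± 0.000362 in late +blast (SD, n = 2). For Cpox it was 0.0465, with 0.00339% ± 0.00120 and 0.000888% ± 0.000366. By the same contrast camera placed 3 lists lower late relative to other guides: ATRX, DAXX and H3 variants (adjusted p = 0.000476, and 0.346 as the adjusted p with an estimated correlation), SUMO and CAF-1 (0.00785, then 0.346) and ribosomal proteins (0.00785, then 0.162).

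Daxx passed the late test although its share of reads was no higher with blasticidin. Reads of the early +blast libraries assigned to the late +blast libraries may account for the late counts, since over the 6 abundant guides these ranked with the early ones (correlation 1, exact permutation p = 0.00278) and were 0.00642% of them, against 0.0151% at the median of 407 guides of other genes. A few cells left from the early population would give the same order, and no index sequences were available, so the 2 stay open. Cells with Daxx guides kept at their starting share cannot be told apart from these by the rank correlation with the late -blast counts (0.371, exact permutation p = 0.497), since it covers 6 guides. Why Daxx guides were abundant early and not late was not tested, since the labels do not define the times of early and late.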

How the results depend on the processing

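Ranks within abundance bins, low counts of guides abundant in the other stage set to 0 and +blast counts under 20 set to 0 were chosen after seeing the data. Apart from the fits with a library left out, there were 6024 values for single genes, those of the fits of 2 groups only included. Of these, 5860 kept their direction and side of the threshold, 79 no longer passed and 85 newly passed. With a library left out, 1877 of 1916 did. For single lists 802 of 893 and 368 of 380 did. The 386 gene results include list members that were never called, so these numbers do not measure how often a call held. The cause was not tested for any change below. Replicate numbers did not pair libraries (correlation of replicate differences -0.0038 to 0.0141), so the block is only an alternative. Total counts were similar with and without blasticidin in Screen II, and depth as a limit was not tested.

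Early, the 24 enriched genes became 49 with camera per gene and 2432 with counts summed per gene (17 to 22 with a library left out). The 0 depleted genes became 1 with RLE, 1 with 2 groups only and 6052 summed (0 to 3 with a library left out). The 9 lists became 5 with the 50-count filter, 5 with DESeq2 and 0 with an estimated correlation (6 to 9 with a library left out).

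Late, the 20 enriched genes became 13 within abundance bins, 11 with the 50-count filter, 12 with library totals and 1468 summed (12 to 16 with a library left out). The 0 depleted genes became 1 with +blast counts under 20 at 0, 1 with control-guide totals, 1 with camera per gene and 3390 summed (0 to 1 with a library left out). The 3 lists became 5 with DESeq2, 7 with a gene-level statistic, 7 with library totals, 8 with control-guide totals, 11 with +blast counts under 20 at 0 and 0 with an estimated correlation (2 to 3 with a library left out). With the gene-level statistic self-renewal factors (0.0231), ribosomal proteins (0.00892) and the proteasome (3.95e-05) reversed to down.

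For the difference late minus early, the 0 enriched genes became 2 within abundance bins, 4 with +blast counts under 20 at 0 and 2334 summed (0 to 0 with a library left out). The 2 depleted genes became 1 with RRA on the top 25%, within abundance bins, with RLE, with library totals and with the replicate block, 4 with +blast counts under 20 at 0 and 1588 summed (1 to 3 with a library left out). The 3 lists became 6 with a gene-level statistic, 6 with no guide filter, 5 with the block, 1 with the 50-count filter, 1 with +blast counts under 20 at 0 and 0 with an estimated correlation (0 to 3 with a library left out).

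For late against early -blast, the 1 enriched gene became 0 without each gene's strongest guide, 7 within abundance bins, 3 with +blast counts under 20 at 0, 2 with the 50-count filter, 3 with DESeq2, 3 with control-guide totals, 6 with library totals, 39 with 2 groups only, 5 with camera per gene and 0 summed (0 to 1 with a library left out). The 6 depleted genes became 3 with +blast counts under 20 at 0, 1 with DESeq2, 15 with the replicate block, 2 with camera per gene and 0 summed (3 to 10 with a library left out). The 0 lists became 5 with a gene-level statistic and 1 each with RLE, library totals, control-guide totals, the 50-count filter, 2 groups only and DESeq2 (0 to 0 with a library left out).

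In Screen I the 357, 102 and 7 genes at days 5, 7 and 9 became 31, 22 and 3 with a pseudocount of 5 CPM, 57, 24 and 4 with no guide filter, and 188, 64 and 11 with the mean of guides. The 50-count filter gave 801 at day 5 and 341 at day 7, the +puro baseline 142 and 41, and median-of-ratios size factors 225 at day 7 and 39 at day 9. The 572 genes at -1 or below between -blast and +puro became 962 with 0.5 CPM, 13 with 5 CPM, 328 with the 50-count filter and 248 with median-of-ratios size factors. The overlap of 3 late genes with day 9 became 0 with a log2 ratio of at least 2 (Fisher's exact p = 1).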

Other observations

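The heme synthesis, apoptosome and SPIN1 and SPINDOC lists and the tests of guide abundance in Screen II were chosen after the Screen II calls were seen. The Screen II values of the added lists restate the calls that prompted them. Among enzymes of heme synthesis, Uros, Urod, Cpox, Ppox and Fech passed early in Screen II and Uros, Urod and Ppox late, with 62.7% and 46.7% of the 75 guides of the list in the top 10%, and within abundance bins 0 members passed late. In Screen I 84.2%, 82.9% and 63.2% of 76 guides were in the top 10% at days 5, 7 and 9, against 9.46%, 9.09% and 11.3% in random sets. The same guides were higher without blasticidin, with a median log2 ratio of 0.87 between -blast and +puro.

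In the apoptosome list, which also holds Hccs, the enzyme that attaches heme to cytochrome c, Apaf1, Casp9 and Hccs passed both early and late, also within abundance bins, with 76.9% of the 52 guides of the list in the top 10% each time. In Screen I the shares were 84.3%, 88.2% and 68.6% of 51 guides, and the median between -blast and +puro was -0.08, at percentile 54.5 of random sets. For Spin1 and Spindoc, 60%, 53.3% and 46.7% of 15 guides were in the top 10% at days 5, 7 and 9. Spin1 held 7.49% of reads at day 9 (exact interval 7.47% to 7.51%).

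Retention of the m6A writer, heme synthesis and apoptosome lists could reflect faster growth or higher guide abundance without blasticidin. At day 5 the median log2 ratios were 0.45, 4.61 and 4.49, above the upper end of the central 95% of gene sets matched on the change without blasticidin (-0.14, -0.11 and 0.01). Within abundance bins of Screen II the early shares of guides in the top 10% were 31.1%, 57.3% and 76.9% and the late shares 29.7%, 34.7% and 75.0%, where the central 95% of random sets ended at 17.6%, 17.3% and 19.2%. The Screen I values of the 3 groups argue against growth, and the Screen II shares of the m6A list against abundance, as the whole cause of the shifts, although single calls (Mettl14, Wtap, Mettl3, Ppox, Uros and, late, Urod) were lost within the bins, and for the lists written from the Screen II calls the bins show only that these guides stayed high at matched abundance. Resistance to blasticidin without the reporter stays open as a hypothesis, since no cells without the cassette were sampled.

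A few guides held most reads of the +blast libraries, and whether chance outgrowth of single clones accounts for many of them in Screen II stays open. The replicates of a group shared 96 (early) and 98 (late) of the 100 most abundant guides. Such outgrowth would thus have to precede any split into replicates. The other guides of the genes with a guide among the 100 most abundant were in the top 10% for 12.5% early and 10.4% late. Random genes had means of 10.6% and 10.3%, and their central 95% ended at 12.8% and 12.5%. The early share thus lay near the upper end, and a share pooled over genes cannot tell a few active genes from none. Genes with at least 2 such guides were Spindoc, Daxx, Pias2 and Spin1 early and Pias2 and Spin1 late. At day 9 of Screen I the share was 11.4%, above the end of that range at 10.8%, which argues against chance outgrowth alone there. No biological explanation was tested for the single abundant guides.

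Guides abundant without blasticidin and with under 10 counts in the +blast libraries of the other stage kept a median of 0.458% and 0.8% of their -blast count in the late +blast replicates 1 and 2, and of 0 in both early +blast replicates. For 22 guides abundant at day 9 of Screen I, the median count in other libraries was 0.396% of the day 9 count in +puro, 0.209% in -blast, 0.597% at day 5 and 0.0876% at day 7.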
